A study of Mus musculus with 24 samples.

How the data were processed

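RNA from 24 mouse kidneys in 4 groups of 6 was extracted with RNeasy kits, and 2 µg per sample went into libraries made with the NEBNext Ultra II RNA kit, per the labels' protocols. Whether the libraries or the counting kept the strand was not given in the sources used here. Reads were quality-checked, aligned and counted per gene with FastQC, STAR, SAMtools and featureCounts and normalized with DESeq2 against GRCm38.p6, per the submitters' processing notes, which give no versions.

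The deposited signal values are normalized counts per gene, which the authors made by dividing gene counts by 1 size factor per library. Multiplying by that factor (0.740 to 1.31) gave whole reads for 100% of values within 0.001, and these recovered reads gave the depth per library and the input of the count models. A second deposited table holds the authors' own comparison for selected genes, with the mean signal, a shrunken log2 fold change and its standard error as deposited by the authors. The same deposited table gives an s-value per gene, a p-value-like measure of the chance of a wrong sign. The sign of that table follows PolgD257A against Polg+/+ after B-IRI for all of its genes kept here. Each deposited column of per-sample values was matched to its sample by group and replicate number. Column names that read Ctrl, Mut and SurgBIR were taken to mean Polg+/+, PolgD257A and B-IRI. This reading is inferred from the names, no source used here states it, and every comparison rests on it.

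The count table has 55416 gene IDs, of which 52088 come with a symbol. Without ID versions 52083 (93.99%) were found in GENCODE M21, the GRCm38 annotation at hand, but 35 had the same ID version and 25 of 1393 genes of the authors' table had the same start. The annotation behind the values therefore differs from GENCODE M21. Coordinates in the text are those of GENCODE M21 on GRCm38, used for location and overlap only, and none from the deposited table are printed.

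The main test was limma-trend (R 4.3.3, limma 3.58.1) on log2(normalized count + 1) with a mean per group over all 24 libraries, for genes with at least 10 normalized counts in at least 6 libraries (17430 genes). The pseudocount understates changes of low genes. Contrasts were B-IRI against sham in each genotype, PolgD257A against Polg+/+ under each surgery, and the surgery by genotype interaction, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. The design and the alternatives were fixed before the data were examined, except where stated.

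Before the data were examined 47 gene lists with 891 entries were written (890 entries found), covering kidney cell types, injury, immune and stress programs, nucleotide metabolism and mitochondrial functions. The 45 lists with at least 4 genes kept were tested with limma's camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, and each method's 225 tests were adjusted together. List medians are over the genes kept. The mean score of each list per library was compared by exact two-sided permutation over 924 relabelings, with 180 tests adjusted together, and 20 tests of library measures were treated likewise.

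Named genes follow a rule fixed before the data were examined. For each contrast these are the 8 largest rises and the 8 largest falls past the threshold with a mean of at least 100 normalized counts and a symbol, leaving out predicted genes and pseudogenes. For each described list up to 4 members with the smallest adjusted p and those moving against the list were eligible. Polg, Havcr1 and Lcn2 were included in every contrast. The 5 largest changes of the authors' deposited table, among its genes with a mean of at least 100 normalized counts, were added for PolgD257A against Polg+/+ after B-IRI. Genes that overlap another on the opposite strand are uncertain without strand-aware counting, and among those named these include Polg, Hddc3, Egf, Adamts4, Rhobtb1, Impdh2, Paics, Ppat, Cp, Col4a1, Sirt3, Esrra, Shmt2, Ndufs1, Kmo and Nfkb2. Pde6a, G6pdx, Junb, Csf1r and Ak3 are further examples. Rnf24 overlaps Snrpert on its own strand. Results for some genes that this rule selects are not reported here.

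Alternatives were pseudocounts of 0.5 and 5, no filter, a filter of 50 normalized counts, TMM scaling, quantile normalization, library weights, robust empirical Bayes, only the 12 libraries compared, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. Thinning the recovered reads to the lowest library total (16689284) and leaving out each library in turn from list scores were added after the data were seen. Models were tested on simulated counts with known changes, and 100 splits of the libraries per contrast, the real split included, were compared. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 was used for the remaining computations and Matplotlib 3.10.9 for plots. Raw reads were not analysed here.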

Results

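RNA was sequenced from 24 mouse kidney libraries in 4 groups of 6. The groups cross the surgery, sham or the ischemia reperfusion injury that the labels call B-IRI, with the genotype of Polg. Polg encodes the catalytic subunit of the DNA polymerase that copies mitochondrial DNA. PolgD257A carries a change that removes the proofreading activity of this polymerase, so that mitochondrial DNA gathers point mutations. The Polg+/+ animals were littermates. The design text asks how such mutations contribute to kidney injury after ischemia reperfusion, and the series title names nucleotide biosynthesis. The labels call the 6 libraries of each group biological replicates, and the sex, the age and the time after surgery were not given in the sources used here.

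The libraries held 16689284 to 26341004 reads assigned to genes. Sham Polg+/+ libraries were the shallowest, with 16689284 to 19737994 reads. Sham PolgD257A libraries held 20843184 to 25858504 reads, B-IRI Polg+/+ libraries 19853485 to 25355776 and B-IRI PolgD257A libraries 18669806 to 26341004. In depth, sham Polg+/+ libraries overlapped with neither the sham PolgD257A nor the B-IRI Polg+/+ libraries (for each, exact two-sided permutation p = 0.002165, the smallest that 924 relabelings of 6 against 6 can give, adjusted p = 0.00618 over 20 library measures). Between 24120 and 25484 genes had at least 1 read per library. The share of reads from mitochondrial genes was 10.02% ± 0.406 in sham Polg+/+, 10.6% ± 0.308 in sham PolgD257A, 9.01% ± 0.367 in B-IRI Polg+/+ and 8.57% ± 0.242 in B-IRI PolgD257A (SD, n = 6). Fold changes below are on the log2(normalized count + 1) scale, and each contrast of 2 groups compares 6 libraries with 6. Their limma standard error (SE) uses 1 variance per gene pooled over all 24 libraries. It is therefore the same for a gene in sham and in B-IRI, whatever the spread within those groups. Adjusted p-values come from limma's moderated two-sided test over 17430 genes.

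Polg mRNA itself (ENSMUSG00000039176.18, chromosome 7, 79446231 to 79466362 on the minus strand of GRCm38 as annotated in GENCODE M21) differed little between the groups. Its mean normalized count was 1060 ± 24.3 in sham Polg+/+, 1046 ± 52.8 in sham PolgD257A, 1078 ± 42.2 in B-IRI Polg+/+ and 1137 ± 51.5 in B-IRI PolgD257A (SD, n = 6). The genotype difference was log2 -0.02 ± 0.04 in sham (adjusted p = 0.95) and 0.08 ± 0.04 after B-IRI (adjusted p = 0.16), neither of which passed, while B-IRI against sham in PolgD257A did (0.12 ± 0.04, adjusted p = 0.012). Because D257A is a codon change that need not alter the amount of mRNA, this level does not check the genotype labels. Fanci overlaps Polg on the other strand, and the strandedness of the counting was not given in the sources used here. On the first principal component, which held 56.7% of the variance, the sham groups lay together (-41.3 ± 3.06 and -40.4 ± 1.60), B-IRI Polg+/+ libraries lay at 21 ± 12.8 (3.55 to 33.7) and B-IRI PolgD257A libraries at 60.8 ± 9.45 (SD, n = 6). There the B-IRI groups spread more widely than the sham groups, a difference in spread that the pooled SE does not carry.

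**Figure D1:**
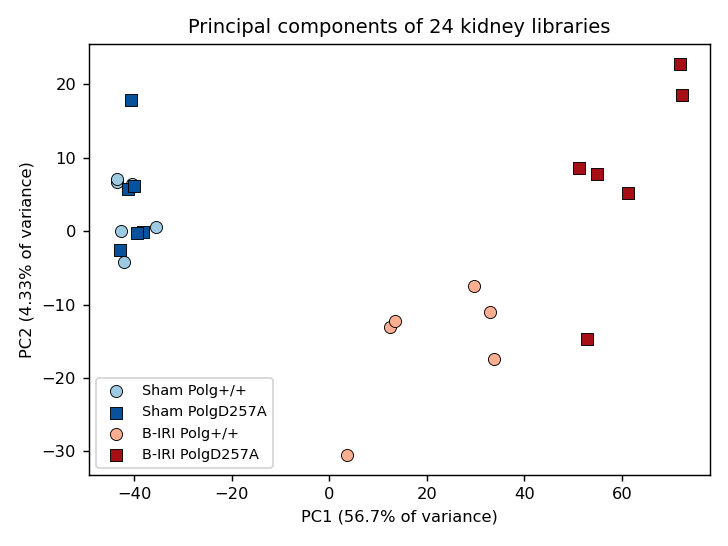
Each point is a library on the first (56.7% of variance) and second (4.33%) principal components of log2(normalized count + 1), with 6 libraries in each of the 4 groups. Both sham groups lie near -41 on the first component, and the B-IRI groups lie apart from them and from each other, with Polg+/+ between 3.55 and 33.7 and PolgD257A at a mean of 60.8.

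The injury response of kidneys with normal Polg was read from B-IRI against sham in Polg+/+. Markers of the injured tubule were among the largest rises. Here and below, the 8 largest rises and falls are those of named genes past the threshold with a mean of at least 100 normalized counts. Some genes with fewer counts changed more, for example Areg (5.96 ± 0.42). Havcr1, which encodes the injury marker KIM-1 (chromosome 11, 46735080 to 46779578), went from 143 ± 29.1 to 14320 ± 7478 normalized counts (SD, n = 6). This was an 88.3-fold change on the fitted scale (log2 6.46 ± 0.24, adjusted p = 5.1e-16). Krt20, an epithelial keratin, rose 58.6-fold (5.87 ± 0.37, adjusted p = 9.2e-12). Lcn2, the secreted lipocalin NGAL (chromosome 2, 32384633 to 32388252), rose 17.99-fold from 81.9 ± 18.9 to 1838 ± 1274 normalized counts (4.17 ± 0.33, adjusted p = 4.0e-10). The protease inhibitor Timp1 (log2 4.22 ± 0.33), the fibrinogen chains Fgb (3.96 ± 0.35) and Fgg (3.74 ± 0.25), the neutrophil chemokine Cxcl1 (3.96 ± 0.27) and the phosphodiesterase gene Smpdl3b (3.76 ± 0.27) completed the 8 largest rises. The 8 largest falls were Pde6a (-2.55), Rnf24 (-2.30), Kif20b (-2.28), the methyltransferase gene Inmt (-2.22 ± 0.12), Itih2 (-2.14), the potassium channel genes Kcng1 (-2.06) and Kcnt1 (-1.95), and the uridine phosphorylase gene Upp2 (-1.92). For all 16 of these genes each of the 6 B-IRI libraries lay beyond every sham library.

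All 26 tubular injury genes rose (26 adjusted over the list alone), with a median log2 change of 1.83 (camera adjusted p = 2.2e-19, adjusted p = 0.22 with an estimated correlation). Of 32 proximal tubule genes, 25 fell and 1 rose (25 and 1 adjusted over the list alone), at a median of -0.65 (adjusted p = 2.1e-10, adjusted p = 0.22 with an estimated correlation). This median shrank to -0.42 under quantile normalization. Among them were Ass1, the arginine synthesis enzyme (-1.50 ± 0.10), Miox, the inositol oxygenase of the proximal tubule (-1.18 ± 0.12), and Cyp2e1 (-1.36 ± 0.14), while the sulfate transporter gene Slc13a1 rose (0.52 ± 0.15, adjusted p = 0.0053). The loop of Henle list did not pass (median -0.16, adjusted p = 0.35), and neither did the distal and collecting duct list (median -0.11, adjusted p = 0.22), by camera, which compares a list with all other genes. The mean scores of both lists, compared between groups alone, were lower in B-IRI. The difference was -0.183 for loop of Henle (exact two-sided permutation p = 0.0238, adjusted p = 0.0461) and -0.179 for distal and collecting duct, with 6 of 6 libraries below every sham library (exact two-sided permutation p = 0.002165, adjusted p = 0.00628). Sham Polg+/+ replicate 6 stood apart in the latter score (0.607 against 0.161 to 0.287), and without it the difference was -0.112 (exact two-sided permutation p = 0.00649, chosen after the data were seen).

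Of 37 cell cycle genes, 22 rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 0.75 (adjusted p = 5.4e-07, adjusted p = 0.50 with an estimated correlation). The replicative helicase subunits Mcm5 (2.07 ± 0.17), Mcm3 (2.11 ± 0.18) and Mcm2 (1.26 ± 0.11) and the licensing factor Cdt1 (1.28 ± 0.12) rose, and the kinesin gene Cenpe fell (-0.80 ± 0.18). Of 27 fibroblast and matrix genes, 20 rose and 2 fell (20 and 2 adjusted over the list alone), at a median of 0.74 (adjusted p = 1.3e-06, adjusted p = 0.41 with an estimated correlation). Among them were the collagen genes Col3a1 (1.85 ± 0.19) and Col1a1 (1.73 ± 0.18), with Dcn (-0.57 ± 0.13) and Ccn2 (-0.68 ± 0.18) lower. Of 30 inflammatory cytokine and NF-kB genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone), at a median of 0.67 (adjusted p = 6.6e-08, adjusted p = 0.27 with an estimated correlation). The macrophage and monocyte markers beside them had a median of 0.30 (adjusted p = 0.15), with Cd68 at 2.08 ± 0.14 and Csf1r at -0.74 ± 0.08, and the 4 neutrophil markers kept had a median of 1.29 (adjusted p = 0.20). The neutrophil score was higher by 1.247 (exact two-sided permutation p = 0.00433, adjusted p = 0.0110), and the macrophage and monocyte score did not pass (exact two-sided permutation p = 0.0996, adjusted p = 0.153). The interferon response list stayed near 0 (median 0.05, adjusted p = 0.70).

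De novo purine synthesis genes moved in both directions, with 8 of 13 higher and 3 lower (8 and 4 adjusted over the list alone) and a median of 0.38 (adjusted p = 0.014, adjusted p = 0.22 with an estimated correlation). Atic (0.65 ± 0.08), Impdh2 (0.48 ± 0.05), Adss (0.46 ± 0.04) and Gart (0.39 ± 0.04) rose, and Adssl1, the muscle form of adenylosuccinate synthase, fell (-0.83 ± 0.13), as did Paics (-0.18 ± 0.04) and Ppat (-0.15 ± 0.05). Of 13 de novo pyrimidine synthesis genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), at a median of 0.27 (adjusted p = 0.0044, adjusted p = 0.23 with an estimated correlation). The CTP synthase gene Ctps (1.02 ± 0.10), Cad, which encodes the enzyme of the opening steps (0.84 ± 0.09), the thymidylate synthase gene Tyms (0.69 ± 0.09) and Dctd (1.38 ± 0.19) were higher. The serine and one-carbon list split into 7 higher and 9 lower of 23 (7 and 9 adjusted over the list alone), and its median (-0.12), mean (0.10) and test direction (down, adjusted p = 0.48) differed in sign. Its score was higher by 0.102 (exact two-sided permutation p = 0.0152, adjusted p = 0.0314). Among its members Phgdh (1.59 ± 0.18), Psat1 (1.48 ± 0.16) and Mthfd2 (1.78 ± 0.18) rose, and Ahcy (-0.73 ± 0.07) and Aldh1l1 (-0.59 ± 0.06) fell. Of 32 integrated stress response genes, 27 rose and 0 fell (28 and 0 adjusted over the list alone), at a median of 1.00 (adjusted p = 2.5e-14, adjusted p = 0.22 with an estimated correlation). These included Atf5 (2.12 ± 0.19), Gdf15 (1.92 ± 0.17) and Eif4ebp1 (1.56 ± 0.12). Impdh2 overlaps Ndufaf3 on the opposite strand, and Ppat and Paics overlap each other.

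Of the 13 mRNAs encoded by mitochondrial DNA, 11 fell and 0 rose (11 and 0 adjusted over the list alone), at a median of -0.28 (adjusted p = 2.9e-05, adjusted p = 0.23 with an estimated correlation). The call was lost under quantile normalization (-0.24). The share of mitochondrial reads was lower too (exact two-sided permutation p = 0.00433, adjusted p = 0.0108, 9.01% against 10.02%), while the share of mitochondrial rRNA was higher, at 0.470% against 0.323% (exact two-sided permutation p = 0.002165, adjusted p = 0.00618). Of 36 nuclear complex I genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone), at a median of -0.15 (adjusted p = 0.0027, adjusted p = 0.74 with an estimated correlation). Of 41 ribosomal protein genes, 40 rose (41 adjusted over the list alone), at a median of 0.37 (adjusted p = 2.1e-13, adjusted p = 0.43 with an estimated correlation).

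In total 3729 genes were higher and 3447 lower in B-IRI than in sham Polg+/+ kidneys, 41.2% of those tested. Of the fixed gene lists, 45 were tested in each of 5 contrasts, and 103 of the 225 tests passed camera with a preset correlation of 0.01. With an estimated correlation camera called 0 of the 225 (smallest adjusted p = 0.22, with 42 under an unadjusted p of 0.05), so no list call holds under it. The rotation test fry, which does not compare a list with other genes, called 26 lists here, and the matching numbers were 38 for injury in PolgD257A, 3 for genotype in sham, 26 for genotype after B-IRI and 20 for the interaction.

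In PolgD257A kidneys, B-IRI against sham was led by Krt20, Havcr1 and Lcn2. Krt20 rose 226-fold (log2 7.82 ± 0.37, adjusted p = 3.4e-15), and Havcr1 rose 186-fold, from 171 ± 25.2 to 31950 ± 4575 normalized counts (SD, n = 6; log2 7.54 ± 0.24, adjusted p = 1.1e-17). Lcn2 rose 83.9-fold, from 80.01 ± 13.2 to 7143 ± 2895 normalized counts (SD, n = 6; log2 6.39 ± 0.33, adjusted p = 2.1e-14). Fgb (5.86), Timp1 (5.78), Fgg (5.44), the actin crosslinker Flnc (5.09) and Serpina10 (4.84) followed. The largest falls among genes with a mean of at least 100 normalized counts were Kcng1 (-4.01 ± 0.26, 16.1-fold lower), Pde6a (-3.87), the amino acid transporter gene Slc7a13 (-3.50 ± 0.18, 11.3-fold lower) and Inmt (-3.48). Next came Egf, the growth factor made by the distal nephron (-3.45 ± 0.25, chromosome 3, 129677565 to 129755316), Kcnt1 (-3.34), Itih2 (-3.26) and the brush border protease gene Mep1b (-3.24). For all 16 genes each of the 6 B-IRI libraries lay beyond every sham library.

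**Figure D2:**
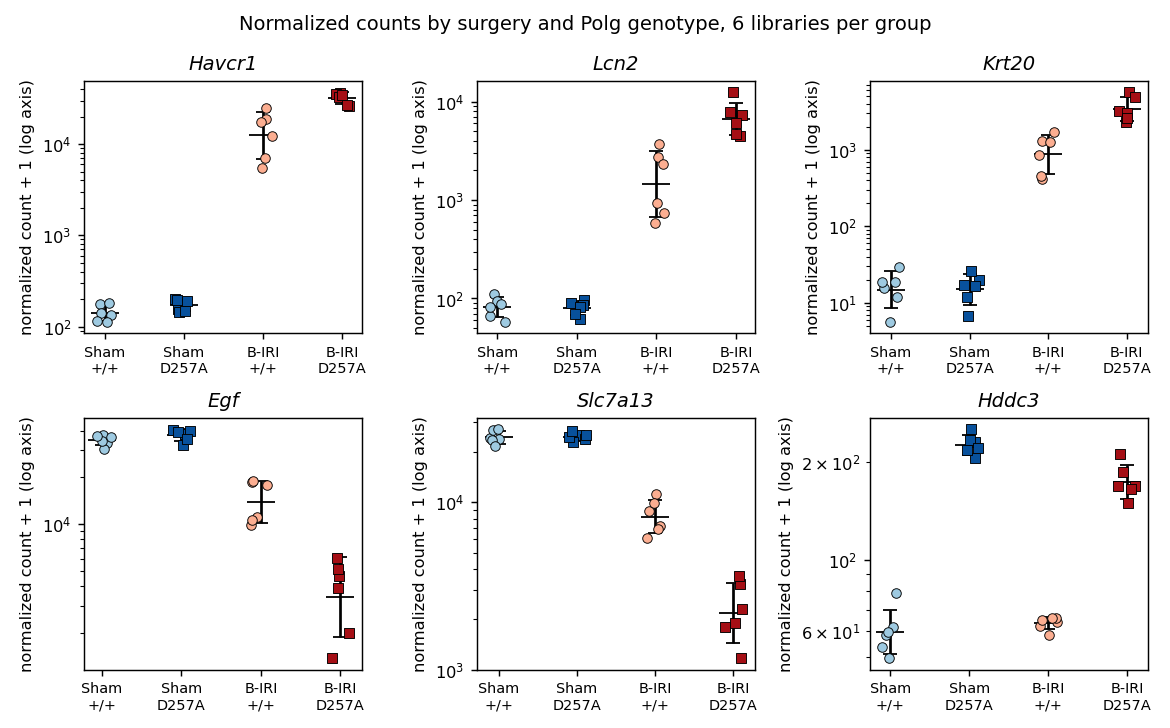
Normalized count + 1 (log axis) of Havcr1, Lcn2, Krt20, Egf, Slc7a13 and Hddc3 in each library, 6 per group, where bars mark the mean and whiskers the SD of the log2 values. Havcr1 means go from 143 and 171 in the sham groups to 14320 in B-IRI Polg+/+ and 31950 in B-IRI PolgD257A, Egf means from 34740 and 37500 to 14520 and 3865, and Hddc3 separates the genotypes under both surgeries.

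All 26 tubular injury genes rose again (26 adjusted over the list alone), at a median of 2.77 (adjusted p = 8.4e-16, adjusted p = 0.22 with an estimated correlation). Of 32 proximal tubule genes, 31 fell and 1, Slc13a1, rose (31 and 1 adjusted over the list alone), at a median of -1.28 (adjusted p = 4.2e-13, adjusted p = 0.22 with an estimated correlation). Miox was at -2.21 ± 0.12 and Ass1 at -2.14 ± 0.10. The loop of Henle list passed camera here, with 10 of 12 genes lower and 0 higher (10 and 1 adjusted over the list alone) and a median of -0.71 (adjusted p = 4.1e-04, adjusted p = 0.43 with an estimated correlation). Fibroblast and matrix genes rose (23 higher and 1 lower of 27, 23 and 1 adjusted over the list alone, median 1.34, adjusted p = 1.8e-08, adjusted p = 0.34 with an estimated correlation). Inflammatory cytokine and NF-kB genes rose too (26 higher and 2 lower of 30, 26 and 2 adjusted over the list alone, median 1.22, adjusted p = 1.8e-08, adjusted p = 0.25 with an estimated correlation). The NF-kB subunit genes Nfkb2 (1.69 ± 0.09) and Relb (1.87 ± 0.14) belong to the inflammatory list. Macrophage and monocyte markers had a median of 0.39 (adjusted p = 0.081) beside them, with Cd68 at 2.41 ± 0.14, Cd14 at 2.55 ± 0.17 and Csf1r at -1.15 ± 0.08. Their score was higher by 0.498, with 6 of 6 libraries above every sham library (exact two-sided permutation p = 0.002165, adjusted p = 0.00628). All 4 neutrophil markers kept rose (4 adjusted over the list alone, median 2.29, or 1.34 with no filter, adjusted p = 0.047, adjusted p = 0.44 with an estimated correlation). The list call was lost without sham PolgD257A replicate 3 (2.26) or 6 (2.14), B-IRI Polg+/+ replicate 6 (2.29), or B-IRI PolgD257A replicate 1 (2.24), 2 (2.28) or 4 (2.00). Cell cycle genes rose with a median of 0.97 (28 higher and 2 lower of 37, 29 and 2 adjusted over the list alone, adjusted p = 4.7e-06, adjusted p = 0.53 with an estimated correlation).

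Respiratory chain genes fell as a block. All 36 nuclear complex I genes were lower (36 adjusted over the list alone, median -0.54, adjusted p = 3.0e-10, adjusted p = 0.45 with an estimated correlation), for example Ndufs1 (-0.79 ± 0.05). All 39 nuclear genes of complexes II to V were lower too (39 adjusted over the list alone, median -0.55, adjusted p = 3.4e-11, adjusted p = 0.44 with an estimated correlation). Their median was -0.31 under quantile normalization. All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone, median -0.56, adjusted p = 4.1e-06, adjusted p = 0.22 with an estimated correlation), with mt-Nd4 at -0.69 ± 0.08. Under quantile normalization their median was -0.32 and mt-Nd4 was at -0.43. The share of mitochondrial reads went from 10.6% to 8.57% (exact two-sided permutation p = 0.002165, the smallest possible, adjusted p = 0.00618), and that of mitochondrial rRNA from 0.367% to 0.612% (the same p and adjusted p). Reads of mt-Nd4 cannot be told from those of mt-Nd4l where these overlap. Of the regulators of mitochondrial biogenesis, 10 of 11 fell and 0 rose (10 and 0 adjusted over the list alone, median -0.54, adjusted p = 8.4e-04, adjusted p = 0.22 with an estimated correlation). Among these were Perm1 (-1.90 ± 0.16), the deacetylase gene Sirt3 (-1.02 ± 0.07) and Tfam, which packages mitochondrial DNA (-0.41 ± 0.05). De novo purine synthesis genes did not pass camera (7 higher and 3 lower of 13, 7 and 3 adjusted over the list alone, median 0.44, adjusted p = 0.12), with Impdh2 at 0.92 ± 0.05 and Atic at 0.88 ± 0.08. Their score was higher by 0.199, with 6 of 6 libraries above every sham library (exact two-sided permutation p = 0.002165, adjusted p = 0.00628). De novo pyrimidine synthesis genes passed (9 higher and 2 lower, 9 and 2 adjusted over the list alone, median 0.28, adjusted p = 0.042, adjusted p = 0.34 with an estimated correlation). Cad was at 1.52 ± 0.09 and Ctps at 1.52 ± 0.10. That call was lost with a filter of 50 normalized counts (0.28), under quantile normalization (0.33), without sham PolgD257A replicate 1 (0.28) and without B-IRI PolgD257A replicate 3 (0.30).

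In total 5260 genes were higher and 5274 lower, 60.4% of those tested. Across 17430 genes the fold changes of both injury responses had a Pearson r of 0.884 and a slope of 1.35 for PolgD257A on Polg+/+, with no library shared between them; genes are not independent replicates. Both responses called 3309 genes higher, against 1125 for independent lists of those sizes, and 3000 lower, against 1043, while 8 genes rose in Polg+/+ and fell in PolgD257A and 3 did the opposite. Of 7176 genes called in Polg+/+, 5392 (75.1%) had a larger absolute change in PolgD257A.

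**Figure D3:**
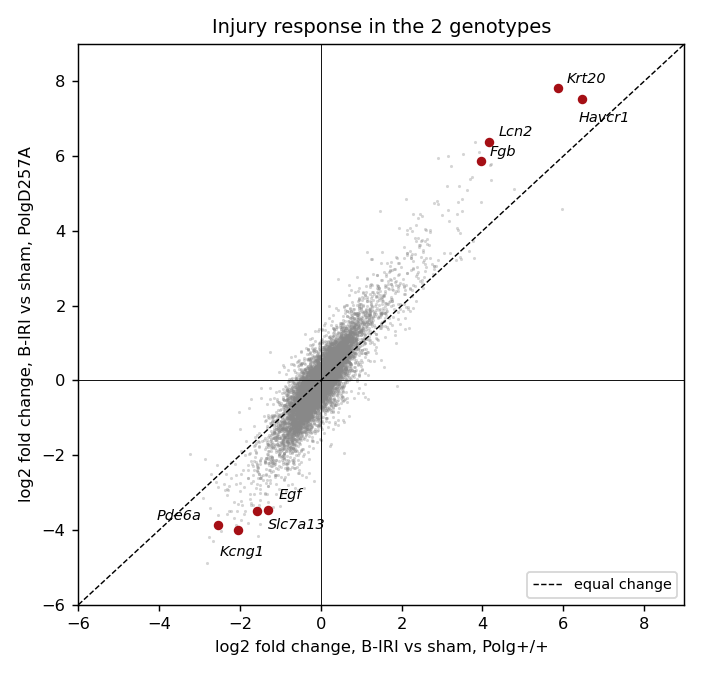
Log2 fold change of B-IRI against sham in PolgD257A (vertical axis) against that in Polg+/+ (horizontal axis), where each of 17430 points is a gene and the dashed line marks equal change. Labelled genes lie farther from 0 in PolgD257A, for example Krt20 at 7.82 against 5.87 and Kcng1 at -4.01 against -2.06.

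Without injury the genotypes differed in few genes. In sham kidneys Hddc3, which encodes a nucleotide hydrolase of the HD domain family (ENSMUSG00000030532.7, chromosome 7, 80343104 to 80350547), was 3.801-fold higher in PolgD257A. It stood at 226 ± 16.3 against 59.4 ± 10.1 normalized counts (SD, n = 6; log2 1.93 ± 0.10, adjusted p = 6.7e-13). The mitochondrial proline tRNA gene mt-Tp (mitochondrial genome, 15356 to 15422 on the minus strand) was 2.46-fold higher, at 13830 against 5655 normalized counts (1.30 ± 0.09, adjusted p = 1.4e-09). Lgals3bp, an interferon-inducible secreted protein (0.76 ± 0.09, adjusted p = 1.0e-05), and Ifi27, another interferon-inducible gene (0.62 ± 0.09, adjusted p = 4.4e-04), were also higher. So were Ngrn, which acts in mitochondrial ribosome assembly (0.51 ± 0.06, adjusted p = 9.9e-06), and Rhobtb1 (0.50 ± 0.08, adjusted p = 0.0013). Lower were Foxi1, the transcription factor of intercalated cells (-0.87 ± 0.12, adjusted p = 4.4e-04), and Gdpgp1 (-0.64 ± 0.10, adjusted p = 0.0011). In each of these genes all 6 PolgD257A libraries lay beyond every Polg+/+ library. The clock gene Cry1 was also higher (0.99 ± 0.20, adjusted p = 0.025). This call was lost with reads thinned to the lowest library total (0.99) and without any of sham Polg+/+ replicates 1 (0.84), 3 (0.99) or 6 (0.96) or sham PolgD257A replicates 2 (0.99), 4 (0.95), 5 (0.94) or 6 (0.93). Hddc3, Ngrn and Gdpgp1 lie within 1 Mb of Polg on chromosome 7, and Man2a2 overlaps Hddc3 on the other strand. The injury genes Havcr1 (0.27 ± 0.24, adjusted p = 0.87) and Lcn2 (-0.02 ± 0.33, adjusted p = 1) did not differ past the threshold.

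**Figure D4:**
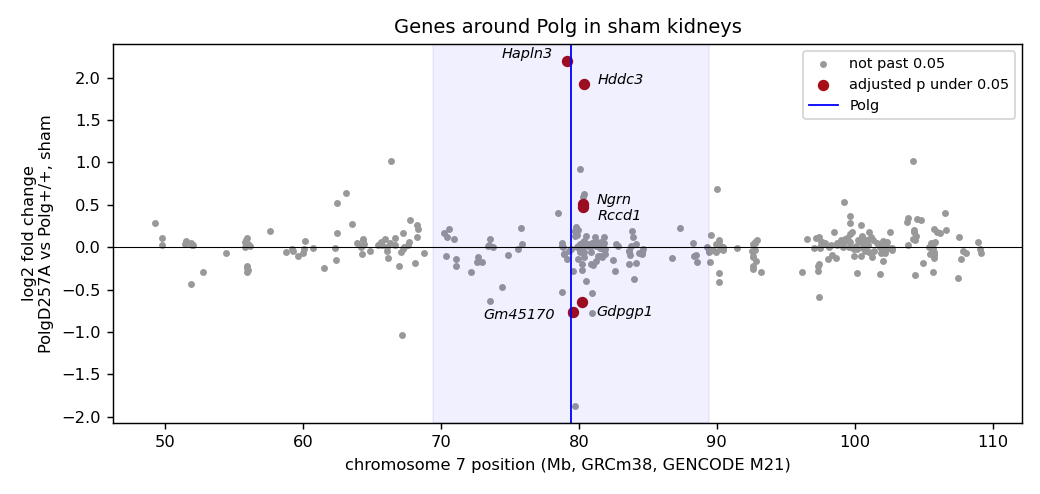
Log2 fold change of PolgD257A against Polg+/+ in sham kidneys for genes on the part of chromosome 7 around Polg (position in Mb, GRCm38 as annotated in GENCODE M21). Polg is marked by a line, 10 Mb on either side are shaded, and the rest of the chromosome is not shown. Red points are the genes past an adjusted p of 0.05, of which 6 lie in the shaded window, including Hddc3 at 1.93.

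The interferon response list was higher in sham PolgD257A as a group. Of its 38 genes 1 passed over all genes and 22 passed adjusted over the list alone, all higher, with a median of 0.29 (camera adjusted p = 9.3e-21, adjusted p = 0.22 with an estimated correlation, fry adjusted p = 0.0099). The mean score of the list was above every Polg+/+ library in 6 of 6 PolgD257A libraries (exact two-sided permutation p = 0.002165, the smallest possible, adjusted p = 0.00628). The mitochondrially encoded mRNAs were higher as a group too, with 0 of 13 past limma's threshold over all genes (7 at an unadjusted p under 0.05), and 6 adjusted over the list alone. Their median was 0.20 (adjusted p = 6.9e-09, adjusted p = 0.22 with an estimated correlation, fry adjusted p = 0.0014). The share of mitochondrial rRNA was higher as well (0.367% against 0.323%, exact two-sided permutation p = 0.0281, adjusted p = 0.0469). By limma neither rRNA gene passed, with mt-Rnr1 at 0.13 ± 0.12 (adjusted p = 0.877) and mt-Rnr2 at 0.28 ± 0.14 (adjusted p = 0.670). Of 18 distal and collecting duct genes, 1 (Foxi1) fell over all genes and 4 adjusted over the list alone, at a median of -0.21 (adjusted p = 5.8e-07, adjusted p = 0.22 with an estimated correlation). The score was below every Polg+/+ library in 6 of 6 PolgD257A libraries (exact two-sided permutation p = 0.002165, adjusted p = 0.00628). Sham Polg+/+ replicate 6 stood apart in this score (0.607 against 0.161 to 0.287) and in Foxi1 (1044 against 537 to 683 normalized counts). The difference in score went from -0.184 to -0.117 without it (exact two-sided permutation p = 0.002165, the smallest that relabelings of 6 against 5 can give, chosen after the data were seen), and the list median to -0.14. The integrated stress response list passed with 0 genes over all genes (7 at an unadjusted p under 0.05) and 3 adjusted over the list alone (median 0.14, adjusted p = 1.1e-06, adjusted p = 0.38 with an estimated correlation). Beside these lists the endothelial markers had a median of 0.16 (adjusted p = 1.9e-04, adjusted p = 0.44 with an estimated correlation), and their score did not pass (exact two-sided permutation p = 0.0671, adjusted p = 0.109). The macrophage and monocyte markers had 0.15 (adjusted p = 0.13) and the neutrophil markers -0.01 (adjusted p = 0.94). Sham PolgD257A libraries were the deeper ones, with at least 20843184 reads against at most 19737994.

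In all 11 lists passed camera between the sham groups, 10 of them higher in PolgD257A. The other 6 had 0 members past the threshold over all genes. Immediate early genes had a median of 0.24 (2 of 13 higher adjusted over the list alone, adjusted p = 6.8e-04, adjusted p = 0.27 with an estimated correlation, score exact two-sided permutation p = 0.0173, adjusted p = 0.0350). Their median was 0.16 without sham Polg+/+ replicate 3 or sham PolgD257A replicate 5. The rest had 0 adjusted over the list alone and small medians. All 5 calls were lost under quantile normalization, and 0 of their 5 scores passed (smallest exact two-sided permutation p = 0.0390, adjusted p = 0.0701). Nuclear complex I genes had 0.07 (35 of 36 positive, adjusted p = 0.0013, adjusted p = 0.74 with an estimated correlation), or 0.04 under quantile normalization, 0.04 without sham Polg+/+ replicate 3 and 0.02 without sham PolgD257A replicate 6, each of which ended the call, and 0.11 without sham Polg+/+ replicate 4. Genes of complexes II to V had 0.06 (39 of 39 positive, adjusted p = 0.0018, adjusted p = 0.74 with an estimated correlation), or 0.02, 0.03 and 0.02 under these 3 settings, all lost, and 0.09 and 0.10 without sham PolgD257A replicate 1 or 3. Ribosomal protein genes had 0.06 (41 of 41 positive, adjusted p = 0.0028, adjusted p = 0.76 with an estimated correlation), or 0.03, 0.02 and 0.01, all lost, and 0.09 without sham Polg+/+ replicate 6 and 0.11 without sham PolgD257A replicate 3. TCA cycle genes had 0.05 (adjusted p = 8.4e-04, adjusted p = 0.51 with an estimated correlation) and 0.01 under quantile normalization. Glycolysis and HIF target genes had 0.06 (adjusted p = 0.0028, adjusted p = 0.31 with an estimated correlation) and 0.03 under quantile normalization.

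De novo purine synthesis (median 0.01, adjusted p = 0.76) and de novo pyrimidine synthesis (median 0.06, adjusted p = 0.23) did not pass in sham. Both had 0 members past limma's threshold, adjusted over the list alone or over all genes, and 0 at an unadjusted p under 0.05. Tubular injury genes (median 0.04, adjusted p = 0.58) and proximal tubule genes (median 0.05, adjusted p = 0.10) did not pass either. In total 15 genes were higher and 7 lower by limma, or 25 and 12 with only the 12 sham libraries in the fit. On recovered reads edgeR gave 14 and 6 and DESeq2 45 and 14. By limma 1280 genes had an unadjusted p under 0.05. In a simulation of this comparison with 17054 genes the test recovered 44% of genes changed by log2 0.32, 80% of those changed 1.5-fold and 96% at 2-fold, so smaller differences could be missed at this depth and number of libraries. Here and in the simulation of the interaction below, 50 genes per fold were changed, none of them from the lowest counts. Each gene had a single dispersion for all groups. The rates need not hold for low genes or for other numbers of changed genes.

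After B-IRI, the comparison the design text is about, the genotypes differed widely. Lcn2 was 4.61-fold higher in PolgD257A (log2 2.20 ± 0.33), followed by Fgb (2.09 ± 0.35), Krt20 (1.96 ± 0.37) and the cytokine gene Lif (1.96 ± 0.31). Also higher were Fga (1.79 ± 0.26), Fgg (1.69 ± 0.25) and Flnc (1.65 ± 0.34). Havcr1 was 2.53-fold higher (1.34 ± 0.24, adjusted p = 1.7e-04). Lower in PolgD257A were Nccrp1 (-2.40 ± 0.48), Egf (-2.03 ± 0.25, adjusted p = 2.0e-06, 3865 ± 1838 against 14520 ± 4375 normalized counts, SD, n = 6) and the calcium-binding parvalbumin gene Pvalb of the distal convoluted tubule (-2.01 ± 0.35). So were Kcng1 (-1.96 ± 0.26), Mep1b (-1.95 ± 0.25), Slc7a13 (-1.91 ± 0.18, adjusted p = 1.4e-07), Tmem207 (-1.88 ± 0.29) and Kcnt1 (-1.71 ± 0.31). Less abundant genes such as Vgf changed more (2.96 ± 0.50). For 3 of the 7 genes from Lcn2 to Flnc and 4 of the 8 from Nccrp1 to Kcnt1 every PolgD257A library lay beyond every Polg+/+ library, and for all 15 each of the 6 lay beyond the Polg+/+ mean. Nccrp1 overlaps Samd4b on the same strand, so its reads are uncertain.

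Tubular injury genes were higher in PolgD257A, 23 of 26 over all genes (25 adjusted over the list alone), at a median of 0.99 (adjusted p = 1.5e-13, adjusted p = 0.22 with an estimated correlation). Gdf15 (1.41 ± 0.17), the keratin gene Krt8 (0.89 ± 0.12) and the ceruloplasmin gene Cp (0.63 ± 0.08) were among them. Nephron genes were lower. Of 32 proximal tubule genes, 26 were lower and 1 higher (26 and 1 adjusted over the list alone), at a median of -0.59 (adjusted p = 2.1e-13, adjusted p = 0.22 with an estimated correlation). They included Miox (-0.97 ± 0.12), Ass1 (-0.79 ± 0.10) and the angiotensin converting enzyme gene Ace (-0.72 ± 0.09). The higher gene was Slc13a1 (0.39 ± 0.15, adjusted p = 0.045). Its call ended with no filter, with robust variance shrinkage and with the replicate number as a block (0.39 each). It also ended without sham Polg+/+ replicate 1 or 3 or sham PolgD257A replicate 4 (0.39 each), B-IRI Polg+/+ replicate 1 (0.35), 3 (0.40) or 4 (0.31), or B-IRI PolgD257A replicate 1 (0.36), 2 (0.27), 4 (0.37) or 5 (0.38). All 12 loop of Henle genes were lower (12 adjusted over the list alone), at a median of -0.55 (adjusted p = 1.4e-08, adjusted p = 0.23 with an estimated correlation). Slc12a1, the furosemide-sensitive cotransporter (-1.37 ± 0.22), and the potassium channel gene Kcnj1 (-0.72 ± 0.11) were among them. Of 18 distal and collecting duct genes, 12 were lower and 1, the calcium channel gene Trpv5 (0.56 ± 0.14), was higher (14 and 1 adjusted over the list alone), at a median of -0.45 (adjusted p = 3.3e-06, adjusted p = 0.23 with an estimated correlation). The 8 kidney genes that are usually higher in males, Slc7a13 among them, were all lower (8 adjusted over the list alone), at a median of -0.89 (adjusted p = 3.6e-07, adjusted p = 0.22 with an estimated correlation).

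Lists of nuclear genes for mitochondrial proteins were lower. Of 36 nuclear complex I genes, 31 were lower and 0 higher (35 and 0 adjusted over the list alone, median -0.32, adjusted p = 1.6e-12, adjusted p = 0.39 with an estimated correlation), for example Ndufs1 (-0.39 ± 0.05) and Ndufa10 (-0.30 ± 0.05). Of 39 genes of complexes II to V, 35 were lower and 0 higher (38 and 0 adjusted over the list alone, median -0.30, adjusted p = 1.1e-12, adjusted p = 0.41 with an estimated correlation). All 19 TCA cycle genes were lower (19 adjusted over the list alone, median -0.25, adjusted p = 2.1e-11, adjusted p = 0.22 with an estimated correlation), for example Idh2 (-0.43 ± 0.06) and Sucla2 (-0.32 ± 0.05). Of 11 biogenesis regulators, 8 were lower and 0 higher (8 and 0 adjusted over the list alone, median -0.36, adjusted p = 1.3e-04, adjusted p = 0.22 with an estimated correlation). Perm1 was at -1.01 ± 0.16, Ppargc1a, the coactivator PGC-1alpha, at -0.48 ± 0.08, and the orphan receptor gene Esrra at -0.46 ± 0.06. The mitochondrially encoded mRNAs did not pass (median -0.05, adjusted p = 0.15), and 1 of the 13, mt-Cytb, was lower (-0.41 ± 0.11, 1 adjusted over the list alone). The share of mitochondrial reads was 8.57% against 9.01% (exact two-sided permutation p = 0.0368, adjusted p = 0.0566), which did not pass, nor did that of mitochondrial rRNA (0.612% against 0.470%, exact two-sided permutation p = 0.0996, adjusted p = 0.133).

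Matrix and inflammatory genes were higher. Of 27 fibroblast and matrix genes, 22 were higher and 0 lower (23 and 0 adjusted over the list alone, median 0.64, adjusted p = 8.0e-10, adjusted p = 0.31 with an estimated correlation). Ccn2 was at 1.20 ± 0.18 and Col4a1 at 0.68 ± 0.09. Of 30 inflammatory cytokine and NF-kB genes, 17 were higher and 1 lower (18 and 1 adjusted over the list alone, median 0.67, adjusted p = 1.8e-08, adjusted p = 0.25 with an estimated correlation). Relb was at 1.00 ± 0.14 and the adhesion gene Icam1 at 0.77 ± 0.11, and the T cell chemokine gene Cxcl9 was lower (-1.28 ± 0.36, or -0.81 with a pseudocount of 5). Markers of other cells passed camera beside these lists, but the endothelial score (exact two-sided permutation p = 0.0281, adjusted p = 0.0522) and the macrophage and monocyte score (exact two-sided permutation p = 0.113, adjusted p = 0.169) did not pass. The neutrophil score was higher by 1.18 (exact two-sided permutation p = 0.0195, adjusted p = 0.0390). Endothelial markers had 8 of 15 higher and 0 lower (9 and 0 adjusted over the list alone, median 0.29, adjusted p = 0.0018, adjusted p = 0.52 with an estimated correlation). Macrophage and monocyte markers had 6 of 21 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.025, adjusted p = 0.67 with an estimated correlation). Cd14 was at 1.26 ± 0.17, Cd68 at 0.71 ± 0.14 and Csf1r at -0.52 ± 0.08. The list call was lost with a filter of 50 normalized counts (0.26), without B-IRI Polg+/+ replicate 1 (0.20) and without B-IRI PolgD257A replicate 2 (0.27) or 4 (0.25). The 4 neutrophil markers had 3 higher (4 adjusted over the list alone, median 1.22, adjusted p = 0.046, adjusted p = 0.44 with an estimated correlation). This call was lost without sham PolgD257A replicate 3 (1.22), B-IRI Polg+/+ replicate 1 (1.05), 4 (1.13) or 6 (1.20), or B-IRI PolgD257A replicate 1 (1.16), 2 (1.22) or 4 (0.92). Lymphocyte markers did not pass (median -0.31, adjusted p = 0.16). Of 32 integrated stress response genes, 21 were higher and 2 lower (25 and 2 adjusted over the list alone, median 0.52, adjusted p = 2.8e-07, adjusted p = 0.34 with an estimated correlation). Atf3 was at 1.36 ± 0.21 and Eif4ebp1 at 0.76 ± 0.12, and Cth (-0.46 ± 0.08) and Vldlr (-0.26 ± 0.05) were lower. The interferon list had 10 of 38 higher and 1 lower (10 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.0022, adjusted p = 0.67 with an estimated correlation). This call was lost without B-IRI PolgD257A replicate 2 (0.084). Its score did not pass (exact two-sided permutation p = 0.182, adjusted p = 0.246, higher than the Polg+/+ mean in 5 of 6 libraries).

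Genes of nucleotide synthesis differed singly and not as lists. Of 13 de novo purine synthesis genes, 6 were higher and 3 lower in PolgD257A (6 and 3 adjusted over the list alone, median 0.03, adjusted p = 0.42). Impdh2 (0.41 ± 0.05) and Impdh1 (0.54 ± 0.09), which make the guanine branch, were higher, and Prps2, which supplies PRPP (-0.44 ± 0.05), Adssl1 (-0.66 ± 0.13) and Paics (-0.19 ± 0.04) were lower. Of 13 de novo pyrimidine synthesis genes, 2 were higher, Ctps (0.63 ± 0.10) and Cad (0.58 ± 0.09), and 1 was lower (2 and 1 adjusted over the list alone, median 0.03, adjusted p = 0.34). Nucleotide salvage and dNTP supply genes had 4 higher and 4 lower of 25 (5 and 4 adjusted over the list alone, median 0.03 but mean -0.0035 and a test direction of down, adjusted p = 0.80). The mitochondrial adenylate kinase genes Ak4 (-1.07 ± 0.11) and Ak3 (-0.43 ± 0.05) were lower and the uridine-cytidine kinase gene Uck2 higher (0.48 ± 0.07). The serine and one-carbon list passed downward, with 11 of 23 lower and 3 higher (12 and 3 adjusted over the list alone, median -0.17, adjusted p = 0.015, adjusted p = 0.36 with an estimated correlation). Its median was -0.10 under quantile normalization, and its score did not pass (exact two-sided permutation p = 0.0303, adjusted p = 0.0557). The lower genes included Dmgdh (-0.72 ± 0.10), Sardh (-0.64 ± 0.07), Shmt2 (-0.50 ± 0.08) and Mthfd1 (-0.36 ± 0.05). The higher genes were Mthfd1l (0.81 ± 0.16), Mthfd2 (0.71 ± 0.18) and Psat1 (0.54 ± 0.16).

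In total 2487 genes were higher and 2653 lower, 29.5% of those tested. With only the 12 B-IRI libraries in the fit 2278 were higher and 2347 lower. The authors' deposited table of their own comparison lists 1401 genes (651 higher and 750 lower), each with an absolute log2 fold change of at least 0.50 and an s-value of at most 0.0449. Of the 1345 genes of the authors' deposited table kept here, 1345 had the same sign as PolgD257A against Polg+/+ after B-IRI, 1317 passed that test, 915 passed the interaction test, and the Pearson r of fold changes across genes was 0.993. Among genes with a mean of at least 100 normalized counts, the 5 largest changes of the authors' deposited table, as its log2 values, were Fgb (2.00), Kcng1 (-1.91), Egf (-1.85), Lcn2 (1.82) and Slc7a13 (-1.80). The 2 sources share the same libraries, so the overlap is no independent check.

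**Figure D5:**
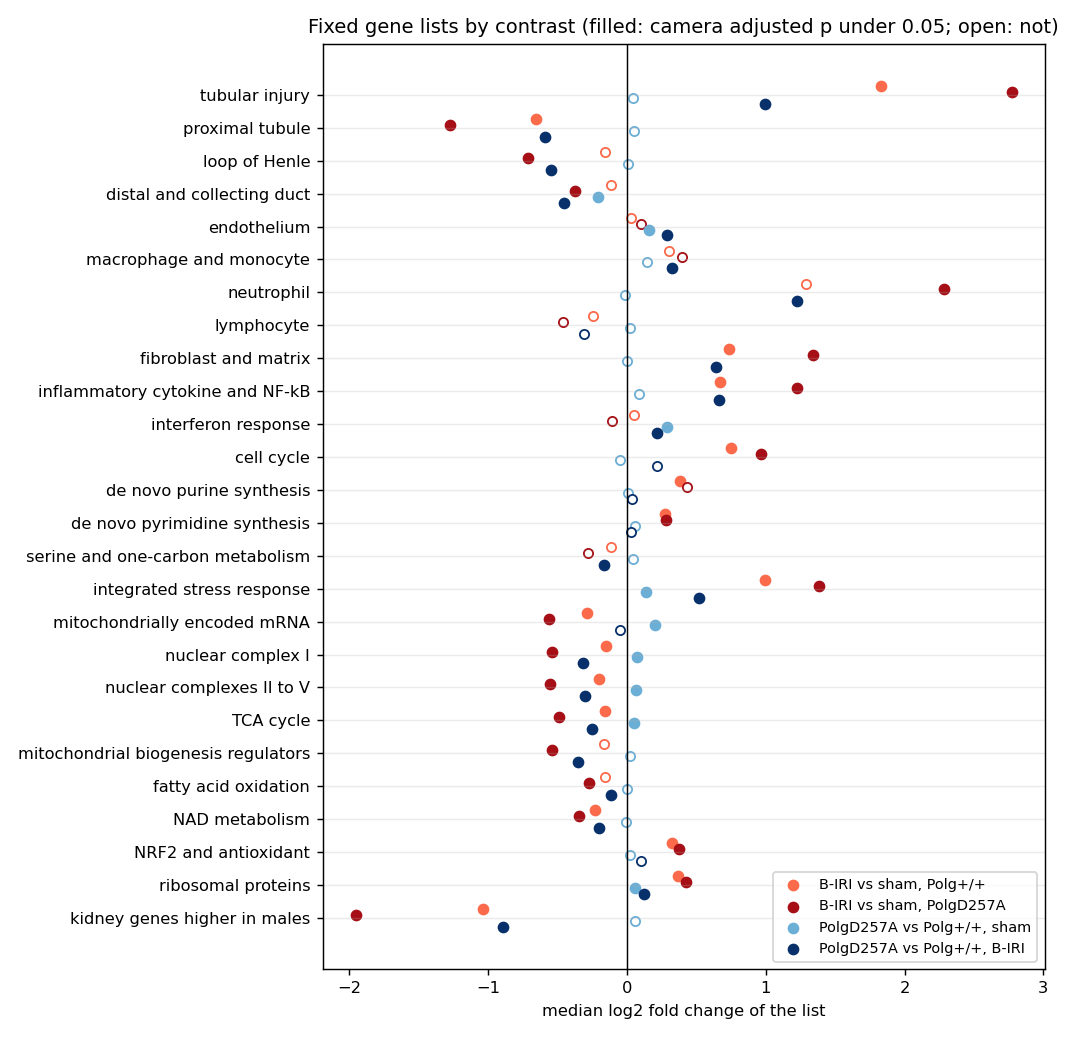
Median log2 fold change (horizontal axis) of the members of 26 described gene lists (vertical axis), out of the 45 tested, in 4 contrasts. A filled point passed camera with a preset correlation at an adjusted p under 0.05 and an open point did not. Tubular injury genes lie at 1.83 and 2.77 for the injury contrasts, at 0.04 for genotype in sham and at 0.99 for genotype after B-IRI.

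The surgery by genotype interaction asks whether the injury response itself differed between the genotypes. The rise of Lcn2 was 4.67-fold larger in PolgD257A (log2 2.22 ± 0.47, adjusted p = 0.0023). Also larger were those of the matrix protease gene Adamts4, 3.82-fold (1.93 ± 0.38, adjusted p = 0.0014), Rasd1, 3.42-fold (1.77 ± 0.32, adjusted p = 6.3e-04), and Fgg (1.70 ± 0.36, adjusted p = 0.0022). For Adamts4 and Rasd1 part of this lay in sham, where PolgD257A means were 9.41 and 54.0 normalized counts against 16.7 and 83.2 in Polg+/+. After B-IRI they were 292 and 234 against 138 and 98.1. The fall of Egf was 4.41-fold deeper (-2.14 ± 0.35, adjusted p = 3.1e-04). Those of Slc7a13 (-1.92 ± 0.26, adjusted p = 9.2e-05), Mep1b (-1.92 ± 0.35), Kcng1 (-1.95 ± 0.36), Pvalb (-2.09 ± 0.50) and Tmem207 (-1.98 ± 0.41) were deeper as well. Nat8f6 (-1.94 ± 0.27) belongs to a family of near-identical genes and overlaps Nat8f5, so its reads are uncertain. Krt20 (1.94 ± 0.52), Fgb (1.90 ± 0.49), Timp1 (1.56 ± 0.46) and Nccrp1 (-2.36 ± 0.67) passed limma but not edgeR (1.86, 2.04, 1.43 and -1.93), and Timp1 was also lost with library weights (1.26). Havcr1 passed at 1.07 ± 0.35 (adjusted p = 0.035). That call was lost with no filter (1.07), library weights (0.88), robust variance shrinkage (1.07), edgeR (0.90) and DESeq2 (0.90). It was also lost without sham Polg+/+ replicate 1 (1.01) or 6 (1.00), sham PolgD257A replicate 3 (1.02) or 5 (1.03), B-IRI Polg+/+ replicate 1 (0.83), 4 (0.91) or 5 (1.07), or B-IRI PolgD257A replicate 1 (1.03) or 4 (1.05).

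Tubular injury genes rose more in PolgD257A (19 of 26 over all genes, 22 adjusted over the list alone, median 0.92, adjusted p = 9.4e-12, adjusted p = 0.23 with an estimated correlation). Proximal tubule genes fell more (22 of 32, with 26 lower and 1 higher adjusted over the list alone, median -0.67, adjusted p = 2.5e-14, adjusted p = 0.22 with an estimated correlation). The same held for loop of Henle genes (11 of 12 lower, 11 adjusted over the list alone, median -0.58, adjusted p = 6.6e-08, adjusted p = 0.25 with an estimated correlation). It held for nuclear complex I genes too (26 of 36 lower, 33 adjusted over the list alone, median -0.38, adjusted p = 2.0e-14, adjusted p = 0.36 with an estimated correlation). Fibroblast and matrix genes rose more (15 of 27, with 18 higher and 1 lower adjusted over the list alone, median 0.67, adjusted p = 1.2e-08, adjusted p = 0.34 with an estimated correlation). Macrophage and monocyte markers (median 0.15, adjusted p = 0.19) and neutrophil markers (median 1.24, adjusted p = 0.067) did not pass beside them. De novo purine (median 0.07, adjusted p = 0.50) and pyrimidine (median -0.02 but mean 0.03 and a test direction of up, adjusted p = 0.72) synthesis lists did not pass. Impdh2 (0.43 ± 0.07) and Cad (0.69 ± 0.13) were positive and Prps2 (-0.47 ± 0.07) and Ak4 (-1.24 ± 0.15) negative past the threshold. In total 1198 genes had a positive and 1582 a negative interaction, 15.9% of those tested. A simulation of the interaction with 17042 genes recovered 16% of genes changed by log2 0.32, 60% of those changed 1.5-fold and 76% at 2-fold, fewer than for the genotype contrasts, since its standard errors are larger (median 0.139 against 0.0985).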

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

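Of the tests in this part, the enrichment of called genes near Polg, the immune marker test and the thinning of reads were chosen only after the results were seen.

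In 5 of 84 groups of 6 values a single library lay far from the other libraries of its group, by its gap to the nearest value relative to the group's range; chance gives about 1 in 20 groups, or 4.2 here. All 5 were in sham Polg+/+. Replicate 6 had the highest Fgb (51.6 normalized counts against 13.5 to 23.7), the highest Foxi1 (1044 against 537 to 683) and the highest distal and collecting duct score (0.607 against 0.161 to 0.287). Replicate 3 had the lowest mt-Tp (3980 against 5544 to 6358), and replicate 1 the lowest total of reads (16689284, or 1.669e+07, against 19285806 to 19737994).

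The remaining results here differ between the genotypes in their response to B-IRI, by limma's interaction test. There were 1198 genes with a positive and 1582 with a negative interaction. By name, the positive log2 differences were Lcn2 (2.22), Krt20 (1.94), Adamts4 (1.93), Fgb (1.90), Rasd1 (1.77), Fgg (1.70), Timp1 (1.56) and Havcr1 (1.07). The negative ones were Nccrp1 (-2.36), Egf (-2.14), Pvalb (-2.09), Tmem207 (-1.98), Kcng1 (-1.95), Nat8f6 (-1.94), Mep1b (-1.92) and Slc7a13 (-1.92). Of these 16 genes, edgeR did not call Krt20 (1.86), Fgb (2.04), Timp1 (1.43), Nccrp1 (-1.93) or Havcr1 (0.90). Havcr1 was also lost without sham Polg+/+ replicate 1 (1.01) or 6 (1.00), sham PolgD257A replicate 3 (1.02) or 5 (1.03), B-IRI Polg+/+ replicate 1 (0.83), 4 (0.91) or 5 (1.07), or B-IRI PolgD257A replicate 1 (1.03) or 4 (1.05).

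Of 26 described lists, 17 passed camera with a preset correlation in the interaction, and 0 with an estimated correlation. Their median log2 differences were 0.92 for tubular injury, -0.67 for proximal tubule, -0.58 for loop of Henle, 0.67 for fibroblast and matrix, 0.58 for inflammatory cytokine and NF-kB genes, -0.28 for serine and one-carbon metabolism, -0.38 for nuclear complex I, -0.36 for nuclear complexes II to V, -0.32 for the TCA cycle, -0.33 for mitochondrial biogenesis regulators, -0.18 for NAD metabolism and -0.98 for kidney genes higher in males. Adjusted p with an estimated correlation was 0.22 to 0.38 for these 12. Under quantile normalization serine and one-carbon metabolism moved to -0.18 and the TCA cycle to -0.22, both still past the threshold. The calls of the other 5 were lost under some settings or without some libraries. The distal and collecting duct list (-0.30, adjusted p = 0.54 with an estimated correlation) was lost under quantile normalization (-0.22) and without sham Polg+/+ replicate 2 (-0.30), 3 (-0.31), 4 (-0.30) or 5 (-0.32), B-IRI Polg+/+ replicate 6 (-0.30) or B-IRI PolgD257A replicate 4 (-0.27). The cell cycle list (0.24, adjusted p = 0.78 with an estimated correlation) was lost with a filter of 50 (0.22), under quantile normalization (0.27), and without sham Polg+/+ replicate 6 (0.21), sham PolgD257A replicate 1 (0.23) or 3 (0.24), B-IRI Polg+/+ replicate 1 (0.20), 4 (0.21) or 5 (0.22), or B-IRI PolgD257A replicate 1 (0.26) or 2 (0.06). The integrated stress response list (0.23, adjusted p = 0.67 with an estimated correlation) was lost without B-IRI Polg+/+ replicate 1 (0.16) or B-IRI PolgD257A replicate 3 (0.18), and the mitochondrially encoded mRNAs (-0.25, adjusted p = 0.25 with an estimated correlation) under quantile normalization (-0.09). Fatty acid oxidation genes (-0.13, adjusted p = 0.74 with an estimated correlation) were lost under quantile normalization (-0.037) and without sham PolgD257A replicate 6 (-0.096), B-IRI Polg+/+ replicate 1 (-0.046) or 3 (-0.12), or B-IRI PolgD257A replicate 1 (-0.073), 2 (-0.098) or 3 (-0.097), and lay at -0.21 without B-IRI PolgD257A replicate 6.

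Chance is argued against as the source of the counts of called genes in each contrast. In 100 splits of the libraries each, 1 split, the real one, gave as many calls. With 100 splits, 1 in 100 was the smallest share that could be reached. Such splits cannot separate the group labels from any other difference that follows them. For the interaction, genotypes were exchanged within each surgery. The real and highest other counts were 7176 and 3627 for injury in Polg+/+, 10534 and 6469 for injury in PolgD257A, 22 and 4 for genotype in sham, 5140 and 3365 for genotype after B-IRI, and 2780 and 980 for the interaction.

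Genes called between the sham genotypes lay near Polg more often than other genes, 6 of 21 with a location within 10 Mb (odds ratio 61.4, Fisher exact two-sided p = 4.3e-09), namely Hapln3, Gm45170, Gdpgp1, Ngrn, Rccd1 and Hddc3. The lower depth of the sham Polg+/+ libraries is argued against, since all 6 stayed past the threshold after thinning. Of the 6, 4 overlap an annotated gene and 0 overlap one called in the same direction, which argues against reads shared with a called gene. Reads shared with an uncalled neighbour stay open, for example Man2a2 beside Hddc3 (means of 813 and 131 normalized counts). The strand and the annotation of the counting are not known. A stretch of chromosome 7 carried along with the edited Polg allele, with strain variants in it, may explain these calls. The 112 uncalled genes in the window leave this open, with a median absolute t of 0.774 against 0.753 in random sets (permutation p = 0.397). No biological explanation for these 6 was tested, and an effect of the mutation on them stays open.

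Interferon response genes and mitochondrial mRNAs were higher in sham PolgD257A (medians 0.29 and 0.20). After thinning the medians were 0.277 and 0.198. For the interferon list this argues against lower depth in sham Polg+/+ acting through low counts. Thinning keeps the expected ratios of abundant genes such as mt-Nd2 (mean 195300 normalized counts). It therefore could not decide this for the mitochondrial mRNAs. Other differences between the libraries that follow depth were not tested. A single sham library is argued against for the interferon list, since its lowest median without any 1 of them was 0.246. The interferon score differed by genotype with exact two-sided permutation p = 0.002165, the smallest the relabelings can give. More immune cells in sham PolgD257A cannot be told apart from a response within kidney cells, since 43 immune markers outside the interferon list had a median of 0.108 with an SE of 0.0692. What raised the interferon genes was not tested, and nucleic acid sensing genes did not pass (median -0.02, adjusted p = 0.81).

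The genotype difference after B-IRI ran along the injury response of Polg+/+ kidneys, with a mean Pearson r across genes of 0.604 (0.460 to 0.712) when the B-IRI Polg+/+ libraries were halved in 20 ways so that both contrasts shared none of them. This fits a larger amplitude of the same response in PolgD257A. A single B-IRI library is argued against as the whole cause, since at least 4125 genes were called without any 1 (4125 without B-IRI Polg+/+ replicate 1). Leaving out 1 library cannot weigh the spread within B-IRI Polg+/+. Its replicates 1, 4 and 5 lay at 3.55, 12.4 and 13.6 on the first principal component, and replicates 2, 3 and 6 at 29.7, 33.7 and 33.0. All B-IRI PolgD257A libraries lay at 51.2 or more. Depth did not differ past the threshold between the B-IRI groups (exact two-sided permutation p = 0.857, adjusted p = 0.902). Thinning, which left 4867 genes called, was thus a weak test of it. In sham the tubular injury score did not differ past the threshold (exact two-sided permutation p = 0.281, adjusted p = 0.364). Of the 22 genes called there between the genotypes, 12 passed with the same sign after B-IRI and 2 with the opposite sign. Of those 12, 6 lie outside 10 Mb of Polg and 6 within it, where a carried-along stretch of chromosome 7 may explain them. Whether the mutation acts on the 6 near Polg stays open. For all 12 the difference in sham argues against amplitude alone. For the other genes, whether genotype acts beyond amplitude cannot be told apart here. With the tubular injury score as a covariate limma called 1 gene outside 10 Mb of Polg, against 4584 without it. Inside that window it called 2, against 41. But that score separated the genotypes (lowest PolgD257A 1.63, highest Polg+/+ 1.42). Differences in the surgery itself, such as the length of ischemia, may also set the amplitude and were not tested.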

How the results depend on the processing

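Thinning and the list scores without 1 library were chosen only after the data were seen; the other alternatives were planned. Named gene results kept direction and side of the threshold in 9523 cases under other settings, lost the call in 189 and turned in 5, and without 1 library in 18982, 525 and 5. List calls were kept in 589 cases and lost in 130 under other settings, 103 of them with an estimated correlation, under which 0 of the fixed gene lists passed, and kept in 2405 and lost in 67 without 1 library. These numbers kept are in part set in advance. In a contrast of 2 groups, leaving out a library of another group cannot move the fold changes, only the pooled variance. Most named genes and all list calls counted here were also picked by the main fit. Requiring an absolute log2 fold change over 1 left 489 higher and 356 lower for injury in Polg+/+, 1021 and 1148 in PolgD257A, 6 and 1 for genotype in sham, 170 and 231 after B-IRI, and 147 and 210 for the interaction, by construction. In sham the main 15 higher and 7 lower became 39 and 16 with library weights, 25 and 12 with only the 12 libraries compared and 45 and 14 with DESeq2, and 4 were lower with a filter of 50. Without 1 library 4 (without sham Polg+/+ replicate 2, sham PolgD257A replicate 2 or 4) to 11 (without sham PolgD257A replicate 1) were lower; the cause was not tested. Without 1 library totals were 6335 to 7319, 10119 to 10588, 15 to 30, 4125 to 5220 and 2102 to 3034 in the order above. After thinning they were 6834, 10239, 19, 4867 and 2613. With the replicate number as a block they were 6835, 10328, 20 (16 higher and 4 lower), 4786 and 2326; the numbers do not pair the samples (correlations of same-numbered libraries -0.326 to 0.174), and not every library correlated best with its own number. The likeness of both injury responses was r = 0.707 with no filter, where many low genes enter. Quantile normalization turned Cat (0.0096), Gpx3 (0.21) and Igfbp7 (0.20) in injury in PolgD257A and Polg (-0.000202) in injury in Polg+/+; the cause was not tested. Lcn2 in sham, not called, was 0.044 with library weights and ranged from -0.11 (without sham Polg+/+ replicate 2) to 0.071 (without replicate 1), above 0 also without sham Polg+/+ replicate 3 or 4 or sham PolgD257A replicate 3 or 6. Scaling moved the median of all genes by under 0.02, which does not bound single genes. In injury in PolgD257A, quantile normalization moved Aldoa from 0.32 to 0.71 and Sdha from -0.60 to -0.20. Irf9 went the other way, from 0.20 to 0.13. The planned covariate from Y-linked genes was not run, since in all 24 libraries Ddx3y had at least 1104 normalized counts and Xist at most 7.418, as in males.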

Other observations

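The mitochondrial tRNA genes were examined as a group only after mt-Tp was seen; the other tests here were planned. In Polg+/+ kidneys B-IRI raised NRF2 and antioxidant genes, which detoxify quinones and heme (median 0.33, 12 of 22 higher and 5 lower, the same adjusted over the list alone, limma camera adjusted p = 0.0031, adjusted p = 0.31 with an estimated correlation). Hmox1 was at 1.98 ± 0.18 and Srxn1 at 1.54 ± 0.11. It also raised pentose phosphate genes, which supply NADPH and ribose for nucleotides (median 0.38, 5 of 7 higher and 0 lower, 5 and 0 adjusted over the list alone, adjusted p = 3.7e-04, adjusted p = 0.22 with an estimated correlation), with Pgd at 1.12 ± 0.08 and G6pdx at 0.79 ± 0.07. Heat shock and ER chaperone genes rose too (median 0.41, 16 of 19 higher and 1 lower, 16 and 1 adjusted over the list alone, adjusted p = 2.3e-07, adjusted p = 0.22 with an estimated correlation), with Hspb1 at 1.82 ± 0.17.

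After B-IRI, NAD metabolism genes were lower in PolgD257A than in Polg+/+ (median -0.20, 8 of 17 lower and 0 higher, 11 and 1 adjusted over the list alone, limma camera adjusted p = 0.0051, adjusted p = 0.31 with an estimated correlation). These included Haao (-0.81 ± 0.10) and Kmo (-0.79 ± 0.09), enzymes that make NAD from tryptophan. Immediate early genes were higher (median 0.70, 10 of 13 higher and 0 lower, 11 and 0 adjusted over the list alone, adjusted p = 8.9e-07, adjusted p = 0.22 with an estimated correlation). Junb was at 0.99 ± 0.16 and Jun at 0.95 ± 0.11, transcription factors induced by stress.

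Of 14 mitochondrial tRNA genes kept, 13 had a positive genotype difference in sham (median 0.44), and 2 passed limma's test, mt-Tp (1.30 ± 0.09) and mt-Tl1 (1.13 ± 0.18). After B-IRI 2 were higher, mt-Tp (0.90 ± 0.09) and mt-Tl1 (0.63 ± 0.18), and 1 lower, mt-Tl2 (-0.58 ± 0.12), with a median of 0.05. Library kits capture such short RNAs poorly, so these reads may come from unprocessed transcripts, which was not tested. The mitochondrial mRNAs had a median of 0.198 in sham after thinning, which at their high counts could not decide on depth.

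Of the 22 genes called between the sham genotypes, 12 passed with the same sign after B-IRI, Lgals3bp (0.68 ± 0.09) and Ngrn (0.53 ± 0.06) among them. Of these 12, 6 lie within 10 Mb of Polg, Ngrn included, and 6 outside it, Lgals3bp included. Rhobtb1 (-0.22 ± 0.08) passed with the opposite sign, and its interaction was -0.72 (limma adjusted p = 1.6e-04).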
